A study of Mus musculus with 8 samples.

How the data were processed

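The data are droplet-based single-cell RNA counts from 8 libraries of mouse duodenal epithelium, 2 in each of the groups homeostasis, atrophy, Yap_WT and Yap_KO. Per the labels' protocols, mice received an intraperitoneal injection of poly(I:C) at 20 mg/kg or of saline, tissue was taken after 24 h, epithelium was released with EDTA, dissociated with Collagenase/Dispase and pipetting, and live cells were sorted by exclusion of a dead-cell dye. Libraries were made with the 10x Genomics Chromium Single Cell 3′ kit (v3 chemistry), which tags transcripts near their 3′ ends with unique molecular identifiers (UMIs). The deposited matrices hold whole-number UMI counts per gene and cell barcode, written by Cell Ranger 4.0.0 per the file headers; the submitters' processing notes name the mm10 build and Seurat 3.2.2, whose role for these files is not given in the sources used here. No cell annotation was used. Each matrix holds 32285 genes, and 32158 of their identifiers were found in the GENCODE M21 annotation of GRCm38 (mm10), which gave the coordinates of all 101 named genes.

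Replicates were compared before they were averaged. Over genes detected in the pair, the chi-square statistic of the counts divided by its degrees of freedom was 71.6 in homeostasis, 102 in atrophy, 133 in Yap_WT and 1070 in Yap_KO, so no pair lay within sampling noise. The 2 replicates of a group shared between 5 and 21 barcodes. Replicate numbers are only numbers in the titles, so libraries were not paired.

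A cell was kept with at least 500 genes detected and at most 25% mitochondrial UMIs. This passed 31650 of 51289 barcodes, and 30593 cells remained after removal of the highest Scrublet doublet scores, 0.8% of cells per 1000 cells in the library (between 38 cells in homeostasis replicate 1 and 203 in Yap_KO replicate 2). Median UMIs per kept cell ran from 26728 in homeostasis replicate 2 to 45652 in Yap_KO replicate 1. Counts were scaled to 10000 per cell, log-transformed, and reduced to 3000 variable genes and 30 principal components with 15 neighbours in scanpy 1.11.5. Interferon-stimulated, MHC, mitochondrial, ribosomal and immediate early genes were left out of the variable genes, with the aim that the response to poly(I:C) would not set the classes. Leiden clustering at resolution 1 over all libraries together gave 26 clusters. They still divided by group. All 1950 and 2944 homeostasis enterocyte-like cells lay in clusters 8, 10, 11 and 18, and all 1735 and 778 of Yap_WT in clusters 3, 5 and 14. A cluster was named for the class with most of its markers raised (at least 1.5-fold, in at least 10% of its cells) and stayed unnamed with fewer than 3 such markers, or with low UMIs and none of its class markers among its 10 leading genes. Names are given as "X-like", since they were rebuilt from markers and not taken from the study. Clusters led by immune markers were kept out of the epithelial sums, and unnamed clusters were kept in the whole-epithelium sum but in no class.

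Raw UMI counts were summed per library and class, since cells are not replicates. A class was tested in a contrast if each of its 4 libraries held at least 20 cells. Sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood fit and test) in a single fit of 8 libraries (fewer where a class lacked cells) and 4 groups, which share an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Unless stated, levels in the text are TMM-scaled CPM computed from the deposited counts, as mean ± SD over 2 libraries. Log2 fold changes are given with standard errors (SE). Paneth marker medians, interferon-stimulated medians of cells and levels within a single cluster are CPM without TMM scaling. A fold against a group with no UMI is a lower bound against 3 counts over the group, and a ratio against 1 to 3 counts is given with its exact 95% counting interval. Shares of cells were tested with the same edgeR test on cell counts with all epithelial cells as the library size, adjusted over 6 classes, and each library's share has an exact binomial (Clopper-Pearson) 95% interval. No exact permutation test can reach 0.05 with 2 libraries against 2.

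Gene lists, 25 in number, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists within a class and contrast. They were interferon-stimulated genes, MHC class I, MHC class II, YAP targets, repair-associated (fetal-like) genes, wound-edge genes, crypt-base genes, proliferation, villus-tip, lower-villus, lipid absorption, carbohydrate and peptide digestion, fatty acid oxidation, cholesterol synthesis, iron and calcium uptake, proximal identity, distal genes, antimicrobial genes, chemokines and NF-kB genes, cell death, p53 targets, unfolded protein response, dissociation genes, glycolysis, and mitochondrially encoded genes. No list in any class or contrast kept its call with an estimated correlation. The lists, cell markers, filters, tests, alternatives and the rule for named genes were fixed before the data were examined; the thresholds for naming a cluster and the alternatives described as added were chosen after. The rule took 13 genes throughout (Yap1, Clu, Msln, Ly6a, Anxa1, Lgr5, Olfm4, Mki67, Apoa4, Alpi, Isg15, Ccn1 and Ccn2), the 6 largest rises and 6 largest falls per contrast in enterocyte-like and progenitor-like sums among called genes without overlap between groups and at least 50 CPM in the higher group, and the 3 members with the smallest adjusted p of each passing list. Some genes that passed these tests are not reported here by name. Genes raised or lowered in atrophy for the test in the second set had an adjusted p below 0.05 and an absolute log2 fold change above 1. The difference of the response between enterocyte-like and progenitor-like sums was tested with limma on within-library differences of log2 CPM.

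The edgeR and list tests of the planned classes, the response difference and the goblet-like share test were tested on simulated data. Gene counts were drawn from 1 mean profile per class, pooled over its libraries, at the real library sizes. For edgeR, 100 genes were changed 2-fold and 100 genes 4-fold. The first set called 11709 genes in the whole epithelium and 5564 in progenitor-like sums. Changes that wide, and genes absent from 1 group, were not simulated, so recovery and false calls there may differ. Of genes changed 2-fold and 4-fold, edgeR recovered 14.6% and 61.2% in the whole epithelium, 7.22% and 43.4% in enterocyte-like sums and 47.5% and 79.8% in progenitor-like sums of the first set. In the second set it recovered 14.3% and 70.1% in the whole epithelium, 45.9% and 82.5% in enterocyte-like sums, 77.0% and 96.9% in progenitor-like sums and 36.0% and 74.5% in goblet-like sums. Unchanged genes called numbered 5, 2 and 0 in the first set and 6, 10, 22 and 5 in the second, in the same order, so some of the calls in classes with few calls are expected to be false. Of 20 unchanged lists none passed in any of these. Those lists were random genes drawn without correlation between members, so they do not test list calls of genes that move together. For the share test, the mean class shares of the second set were used in every library, with a fixed spread. It recovered 35 of 50 simulated 4-fold changes in goblet-like share and called 15 of 250 unchanged shares, so some share calls may be false. The loss of a class as large as the enterocyte-like class in the first set was not simulated. The test of the response difference failed this check: it recovered 115 of 197 genes changed 4-fold but also called 1293 of 11649 unchanged genes, while the same test on sums thinned to equal depth recovered 24 of 54 and called 1 of 3497. It is therefore read from the thinned sums.

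Alternatives covered RLE factors, mitochondrial and ribosomal genes left out, other count filters, DESeq2 1.42.0, fits on 4 libraries, a replicate block, each library left out in turn, thinning to equal depth, other cell filters, no doublet removal, other clusterings and resolutions, and fry or an estimated correlation for lists. Goblet-like, Paneth-like, enteroendocrine-like and tuft-like sums of the first set and tuft-like and gastric mucous-like sums of the second were left out because a library held fewer than 20 such cells. Genes of families with near-identical copies (Defa, Ly6, H2, Ifit, Gsdmc) are reported as uncertain in their split between members.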

Results

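Single-cell RNA sequencing of duodenal epithelium was performed on 8 libraries of C57BL/6J mice aged 8 weeks, with 2 libraries in each of 4 groups. The first set held wild-type mice 24 h after a saline injection (homeostasis) and wild-type mice 24 h after 20 mg/kg poly(I:C), a double-stranded RNA mimic that causes loss of villi in the proximal gut (atrophy). The second set held mice with floxed Yap alleles and no Cre (Yap_WT) and mice with a Vil1-Cre deletion of Yap (Yap_KO), all of them 24 h after poly(I:C). YAP, encoded by Yap1, is the transcriptional coactivator of the Hippo pathway. The series text states that atrophy libraries of the first set came from damaged gut alone, while those of the second set also held distal gut without damage. Levels were therefore compared within a set only.

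The libraries held between 92102352 UMIs (homeostasis replicate 1) and 212027136 UMIs (Yap_KO replicate 1). There were 120639856 in homeostasis replicate 2, 159961056 and 196835296 in atrophy, 146709824 and 137321152 in Yap_WT and 186128672 in Yap_KO replicate 2. Of 51289 barcodes, 30593 cells were kept, between 2166 in homeostasis replicate 1 and 4843 in Yap_KO replicate 2. The groups differed in RNA quality. Mitochondrial transcripts made up a median of 63.5% and 47.7% of the UMIs of all barcodes in homeostasis, against 3.60% and 3.61% in atrophy, 7.46% and 6.25% in Yap_WT, and 3.88% and 9.60% in Yap_KO. The cell filter passed 24.3% and 38.9% of homeostasis barcodes but 88.9% and 89.8% of atrophy barcodes. Kept cells still carried medians of 13.2% mitochondrial UMIs in both homeostasis libraries and 3.5% and 3.53% in atrophy. The labels do not state that the 2 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical, and intervals cover counting error only.

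The first comparison asked how the epithelium differed between homeostasis and poly(I:C)-induced villus atrophy. Enterocyte-like cells, the absorptive cells of the villus, made up 90.4 ± 0.141% of epithelial cells in homeostasis and 0.623 ± 0.156% in atrophy (SD, n = 2 each), 145-fold less (log2 ratio −7.18 ± 0.75 SE, adjusted p = 6.07e-09 by edgeR's quasi-likelihood test on cell counts). Stem and progenitor-like cells went the other way, from 0.978 ± 0.384% to 72.8 ± 3.18% (75.3-fold, adjusted p = 2.43e-08). The share of goblet-like cells, which secrete mucus, rose 5.88-fold to 6.00 ± 0.997% (adjusted p = 0.000834). That of Paneth-like cells, the antimicrobial cells of the crypt, rose 21-fold to 3.46 ± 0.12% (adjusted p = 1.22e-05). Shares sum to a whole, so the fall of the enterocyte-like share raises the other shares even where those cells do not change. A rise in share is therefore not read as more cells of a class. Enteroendocrine-like cells (1.12 ± 0.0354% against 0.539 ± 0.024%, adjusted p = 0.112) and tuft-like cells (0.166 ± 0.0686% against 0.37 ± 0.000707%, adjusted p = 0.112) did not pass the test. Exact binomial 95% intervals for single libraries ran from 89.0 to 91.5% for enterocyte-like cells in homeostasis replicate 1 and from 0.475 to 1.08% in atrophy replicate 1. Unnamed clusters held 6.81% and 6.36% of homeostasis cells and 15.6% and 9.49% of atrophy cells. Shares depended on the cell filter, which removed most homeostasis barcodes. The stricter setting changed the gene minimum and the mitochondrial limit together, so neither was tested by itself. With a limit of 10% and 1000 genes the goblet-like log2 ratio was −0.71 in place of 2.56, the Paneth-like ratio was 0.60 in place of 4.39, and the progenitor-like ratio was 3.05 in place of 6.24. Those limits passed only 165 and 243 homeostasis barcodes, against 2204 and 3353 under the main filter. Which classes lost most cells was not tested. Homeostasis held few of these cells, with 2 and 7 Paneth-like and 14 and 44 goblet-like cells. The Paneth-like ratio was 3.99 and 5.18, and the goblet-like ratio 2.15 and 3.21, without homeostasis replicates 1 and 2.

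**Figure D1:**
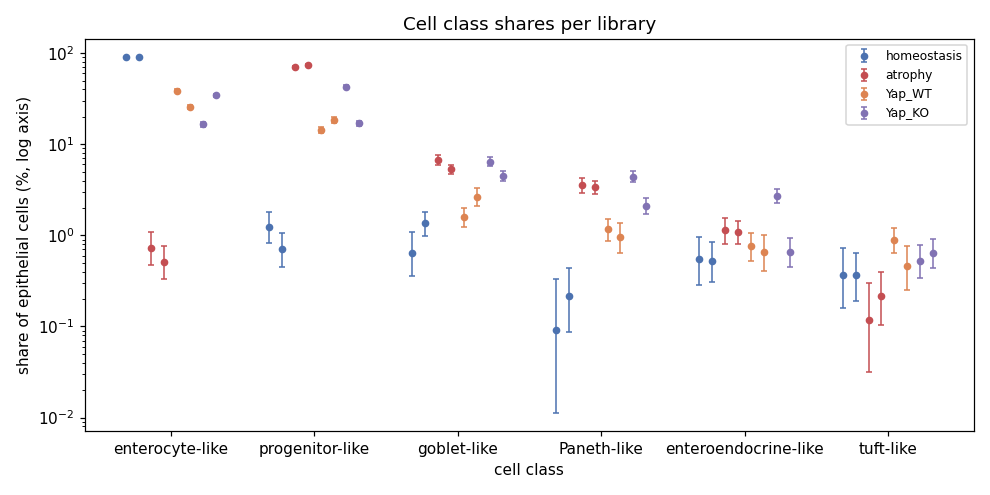
Share of epithelial cells (percent, log axis) that each named cell class held in each of the 8 libraries, 1 point per library coloured by group, with exact binomial 95% intervals as bars. Enterocyte-like cells held 90.3 and 90.5% in homeostasis and 0.733 and 0.513% in atrophy, and stem and progenitor-like cells 1.25 and 0.707% against 70.6 and 75.1%.

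Summed over the whole epithelium, gene levels followed the same division. All 35 proliferation genes were higher in atrophy (median log2 fold change 4.61, camera adjusted p = 1.26e-11, adjusted p = 0.612 with an estimated correlation), including Mki67 (28.1-fold, 4.81 ± 0.32 SE), Top2a (5.01 ± 0.28), Tpx2 (5.28 ± 0.24) and the mitotic kinesin Kif11 (4.43 ± 0.23). Of 24 crypt-base stem cell genes 22 were higher (median 3.2, adjusted p = 2.2e-05, and 0.612 with an estimated correlation), among them the R-spondin receptor gene Lgr5 (25.5-fold), Olfm4 (9.46-fold, log2 fold change 3.24, but 0.33 with adjusted p = 0.283 under the limits of 10% and 1000 genes), Sox9 (4.08 ± 0.25) and Ephb2 (3.74 ± 0.24). All 19 lipid absorption genes (median −4.97, adjusted p = 1.75e-06) and all 25 carbohydrate and peptide digestion genes (median −6.83, adjusted p = 8.84e-09) were lower, each with adjusted p = 0.612 with an estimated correlation. Examples were Apoa4, an apolipoprotein of chylomicrons (221-fold lower, 8005 ± 1229 to 36.2 ± 2.65 CPM, SD, n = 2), Apoc2 (−6.22 ± 0.43), Apob (−4.97 ± 0.46), the peptide transporter Slc15a1 (−8.72 ± 0.72), the sugar transporters Slc2a2 (−8.51 ± 0.48) and Slc2a5 (−7.23 ± 0.47), Khk (−6.98 ± 0.5) and the brush-border phosphatase Alpi (15-fold lower). Villus-tip enterocyte genes (11 of 14 lower, 1 higher, adjusted p = 0.00431) and fatty acid oxidation genes (15 of 19 lower, 1 higher, adjusted p = 0.000564, with Acaa1b at −9.24 ± 0.65, Ehhadh at −4.98 ± 0.36 and Acadm at −2.72 ± 0.24) also passed, both at 0.612 with an estimated correlation.

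Genes linked to repair and to antiviral responses were also higher in this sum. The fetal-like and repair-associated list had 23 of 32 members higher and 5 lower (median 3.45, or 2.54 with genes absent from homeostasis at their bound, adjusted p = 0.000564, and 0.612 with an estimated correlation). The Ly6 family gene Ly6a (Sca-1) rose 6600-fold, from 0.577 ± 0.0705 to 3784 ± 149 CPM (SD, n = 2, adjusted p = 4.5e-06), and Clu, a marker of damage-induced stem cells, 33.3-fold (5.06 ± 1.23, adjusted p = 0.00796, but 0.0575 without homeostasis replicate 1 and 0.0788 with the limits of 10% and 1000 genes). Anxa1 and Msln had no UMI in homeostasis and were at least 2840-fold and 143-fold higher, against a floor of 3 counts over the group. Msln was low and uneven in atrophy (833 and 198 UMIs, 5.49 and 1.07 CPM without TMM scaling). Anxa10 rose by 7.64 ± 0.25 and was among the leading genes of the gastric mucous-like cluster, which had 281 atrophy and 0 homeostasis cells, and Clu stood at 171 CPM there. Wound-edge adhesion and matrix genes (15 of 23 higher, 3 lower, adjusted p = 0.00925, and 0.612 with an estimated correlation) included Plaur (7.44 ± 0.33), Actn1 (4.07 ± 0.18) and Itga2 (2.26 ± 0.12). Of 43 interferon-stimulated genes 35 were higher and 1 lower (median 2.80, adjusted p = 6.25e-06, and 0.617 with an estimated correlation), including Isg15 (4.04 ± 0.45), Bst2 (5.66 ± 0.22), Irgm1 (4.28 ± 0.31) and Ifi44 (5.92 ± 0.46). Antimicrobial genes (14 of 21 higher, 3 lower, adjusted p = 0.0116, and 0.612 with an estimated correlation) included the oxidase gene Duox2 (8.94 ± 0.48), its maturation factor Duoxa2 (8.50 ± 0.49) and the defensin Defa22 (5.33 ± 0.34). All 13 mitochondrially encoded genes were lower (median −2.28, adjusted p = 3.61e-05, and 0.612 with an estimated correlation), for example mt-Nd3 (−2.69 ± 0.17), in libraries that differed in mitochondrial content of kept cells as given above. In total 11709 of 15415 genes were called, 5938 higher and 5771 lower.

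Within stem and progenitor-like sums, interferon-stimulated genes were higher in atrophy. Of 43 tested, 34 were called higher and none lower (39 when adjusted over the list alone). Their median log2 fold change was 5.33 with absent genes at their bound (camera adjusted p = 1.31e-11, and 0.403 with an estimated correlation). Isg15, a ubiquitin-like antiviral modifier (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, GRCm38), rose 401-fold from 2.51 ± 0.36 to 997 ± 70.8 CPM (SD, n = 2; 8.65 ± 0.55 SE, adjusted p = 1.47e-05). Its homeostasis level rested on 3 and 3 UMIs from 27 and 23 cells. The SD there does not show counting error, and the size of the fold is uncertain. The interferon regulatory factor Irf7 rose 80.5-fold, Bst2 43.2-fold and Ifi27l2b 4.57-fold. Rsad2, Ifit3, Ifi44, Isg20 and the chemokine Cxcl10 had no UMI in homeostasis progenitors and were at least 119-, 98.4-, 74.9-, 63.9- and 333-fold higher. The calls of Cxcl10, Ifit3 and Rsad2 rested on both homeostasis libraries: their adjusted p values were 0.124, 0.125 and 0.0971 without replicate 1 and 0.0946, 0.0916 and 0.0705 without replicate 2. MHC class I genes rose in part (13 of 21 higher, 4 lower, 15 and 4 adjusted over the list alone, adjusted p = 0.0183, 0.168 without homeostasis replicate 1, and 0.781 with an estimated correlation), among them H2-D1 (4.01-fold), H2-T23 (7.19-fold) and H2-Q7 (19-fold). Ifit and H2 genes have near-identical copies, so the split of UMIs between members is uncertain.

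The repair-associated list also moved within progenitors, with 19 of 29 members higher and none lower (21 adjusted over the list alone, median 2.60 with absent genes at their bound, adjusted p = 1.35e-08, and 0.403 with an estimated correlation). Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031) stood at 4600 ± 198 CPM in atrophy against 1 UMI in homeostasis, a ratio of 10100 with a counting interval from 1820 to 400000. Its neighbour Ly6c1 was at least 641-fold higher, Anxa1 at least 43.8-fold, S100a6 884-fold and S100a11 18.7-fold. Ly6 genes share near-identical sequence. Clu did not pass (ratio 3.33, interval 0.919 to 27.5, adjusted p = 0.0555), nor did Msln (0.582 ± 0.540 CPM against 0 UMIs, adjusted p = 0.534). Of 23 wound-edge genes 18 were higher and 1 lower (adjusted p = 0.000237, and 0.403 with an estimated correlation), with Zyx 7.50-fold, the integrin Itga3 2.69-fold and Myl12a 1.59-fold. YAP target genes as a list did not pass (6 of 16 higher, 1 lower, adjusted p = 0.0734). Ccn2 (Ctgf) was at least 2.74-fold higher (adjusted p = 0.0189, but 0.103 and 0.0704 without homeostasis replicates 1 and 2), and Ccn1 (Cyr61) did not differ detectably (−0.16 ± 0.43, adjusted p = 0.791). Yap1 itself was 1.99-fold higher (0.99 ± 0.12, adjusted p = 0.000434).

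Absorptive genes were lower in the same sums. Lipid absorption genes fell in 14 of 18 cases and rose in 1 (median −1.73, adjusted p = 3.04e-05), and carbohydrate and peptide digestion genes fell in 17 of 24 and rose in 1 (median −3.06, adjusted p = 1.84e-06). Fatty acid oxidation genes fell in 13 of 19 and rose in 1 (14 and 2 adjusted over the list alone, adjusted p = 0.000706) and villus-tip genes fell in 7 of 13 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00554). The adjusted p was 0.403 with an estimated correlation for each of the 4. The largest falls were in Car4, a membrane carbonic anhydrase (404-fold), Arg2 (167-fold), Adh1 (87.8-fold), Apoc3 (67.6-fold), Adh6a (50.5-fold) and Apoa4 (43.7-fold). Smaller falls were in Khk (20.9-fold), Slc7a8 (16.7-fold), Apoc2 (6.40-fold), Fabp2 (5.10-fold), Ehhadh (4.40-fold), Dgat1 (3.31-fold), Acaa2 (2.99-fold), Apob (2.31-fold), Acadvl (1.98-fold) and Malat1 (1.72-fold). Enterocytes were 90.4% of homeostasis cells, and the homeostasis progenitor sums held RNA of enterocyte genes at 3.86% of the enterocyte level, the 10th percentile over 244 abundant genes measured in the same libraries. After subtraction of that fraction the digestion, lipid, fatty acid oxidation and villus-tip lists kept 7, 7, 9 and 4 lower calls. With the lowest ratio among those genes, 0.753%, subtracted instead, they kept 16, 13, 13 and 7. Car4, Arg2, Adh1, Adh6a, Khk, Slc7a8, Fabp2 and Dgat1 stayed lower. Apoa4 (adjusted p = 0.647) and Apoc3 (adjusted p = 0.545) lost their calls and Apoc2 turned higher (adjusted p = 0.00463), all of which had lain below the subtracted fraction (1.37, 2.6 and 1.35% of the enterocyte level). All 13 mitochondrially encoded genes were lower (median −1.34, adjusted p = 2.87e-09, and 0.403 with an estimated correlation), for example mt-Cytb (2.86-fold) and mt-Nd4 (2.66-fold).

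Crypt-base genes moved in both directions within the class. Their list did not pass (5 of 24 higher, 8 lower, adjusted p = 0.558), with Lgr5 at 14.1 ± 0.849 against 14.7 ± 3.77 CPM (adjusted p = 0.856) and Olfm4 3.28-fold lower (adjusted p = 0.000254). Proliferation genes did not pass (13 of 35 higher, 5 lower, adjusted p = 0.649), and Mki67 stood at 238 ± 5.42 against 232 ± 17.8 CPM (adjusted p = 0.830). Lgr5, Olfm4, Mki67 and other members of these 2 lists were among the markers that named the class. The choice of clusters thus favours similar levels, and these results do not test whether stem cell or proliferation genes changed. The remaining lists did not pass: MHC class II (3 of 7 higher, adjusted p = 0.102), lower-villus (3 of 11 higher, 5 lower, 0.797), cholesterol synthesis (7 of 20 higher, 2 lower, 0.908), iron and calcium uptake (5 of 10 higher, 3 lower, 0.588), proximal identity (1 of 8 higher, 4 lower, 0.0987), distal genes (1 of 7 higher, 3 lower, 0.588), antimicrobial genes (5 of 20 higher, 5 lower, 0.908), chemokines and NF-kB genes (5 of 18 higher, 4 lower, 0.200), cell death (11 of 23 higher, 6 lower, 0.358), p53 targets (4 of 15 each way, 0.797), unfolded protein response (9 of 18 higher, 0.0712), dissociation genes (6 of 19 higher, 10 lower, 0.0734) and glycolysis (9 of 15 higher, 0.114). In all, 5564 of 13150 genes were called, 3136 higher and 2428 lower, and 3214 after thinning to equal depth. Homeostasis contributed only 27 and 23 progenitor-like cells against 2409 and 3513 in atrophy. All of them lay in clusters 6 and 9, where atrophy had 16 and 40 cells. Clusters 1, 4 and 7 held 2235 and 3053 atrophy cells.

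**Figure D2:**
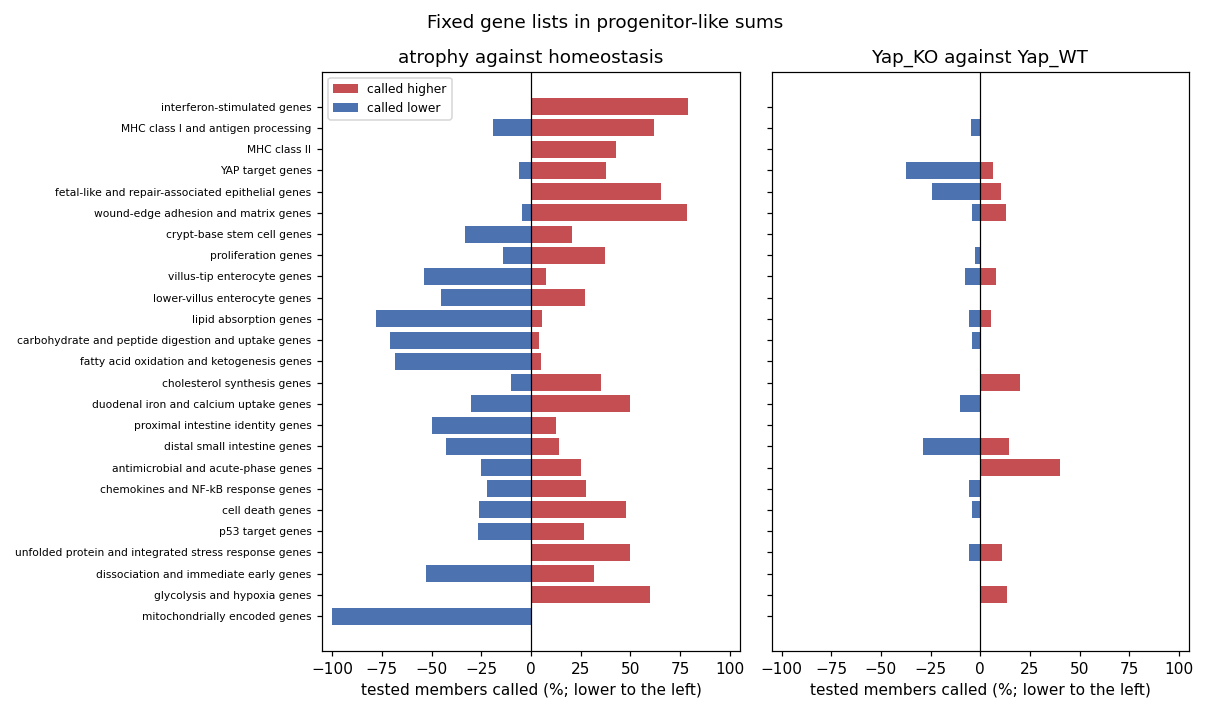
For each of the 25 gene lists, the percent of tested members called higher (red, to the right) or lower (blue, to the left) in stem and progenitor-like sums, by edgeR at an adjusted p below 0.05, for atrophy against homeostasis and for Yap_KO against Yap_WT. In atrophy 34 of 43 interferon-stimulated genes lie to the right and 17 of 24 digestion genes to the left, and in Yap_KO 6 of 16 YAP target genes lie to the left.

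In enterocyte-like sums 2 of 12521 genes were called, both higher in atrophy. Ly6a stood at 1038 ± 751 against 0.488 ± 0.0473 CPM (SD, n = 2; 11.05 ± 0.72 SE, adjusted p = 0.00567), and the antimicrobial lectin Reg3g rose 22.7-fold (adjusted p = 0.0456). No gene was called lower by edgeR, where 1747 genes had an unadjusted p below 0.05 and DESeq2 called 940 genes in all. Of 43 interferon-stimulated genes none was called over all genes and 32 were higher when adjusted over the list alone (median 2.45, camera adjusted p = 8.25e-13, and 0.676 with an estimated correlation), with Isg15 at 748 ± 641 against 47.0 ± 13.7 CPM (adjusted p = 0.124). Antimicrobial genes (10 of 19 higher and 1 lower adjusted over the list alone, adjusted p = 7.14e-07, and 0.160 with an estimated correlation), proliferation (5 of 34, 8.85e-05), wound-edge (4 of 21, 5.76e-05), repair-associated (11 of 26, 0.00145) and MHC class I lists (3 of 21, 0.0192) also passed, the last 4 with adjusted p = 0.676 with an estimated correlation. Apoa4 (−0.58 ± 0.38, adjusted p = 0.521) and Alpi (−0.23 ± 0.26, adjusted p = 0.709), both among the markers that named the class, did not differ detectably. The atrophy libraries held only 25 and 24 such cells. Of these, 23 of the 25 in atrophy replicate 1 lay in the homeostasis clusters 8, 10, 11 and 18, against 22 of 24 of replicate 2 in clusters 3, 5 and 14. Without atrophy replicate 1 the count was 1244, without atrophy replicate 2 it was 1, and without either homeostasis replicate it was 0. Without atrophy replicate 2 the repair-associated, wound-edge and MHC class I lists stood at 0.339 and proliferation at 0.0783. Goblet-like sums of this set were not tested, since homeostasis replicate 1 had 14 such cells.

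The second comparison asked which parts of the atrophy state differ when Yap is deleted from the epithelium. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596) had 6 and 0 UMIs in the Yap_KO epithelium against 2814 and 3151 in Yap_WT (−10.36 ± 0.45 SE, adjusted p = 0.00177). In stem and progenitor-like sums it had 0 and 0 against 1202 and 1694 UMIs, at least 1740-fold lower. In goblet-like sums it was at least 151-fold lower, and in enterocyte-like sums 1 UMI remained (ratio 1540, interval 276 to 60900). The goblet call was lost without Yap_WT replicate 1 (adjusted p = 0.0568) or 2 (0.104). The tags lie near 3′ ends and the labels do not give the deleted exons, so tags outside the deleted part would not report it. In homeostasis and atrophy Yap1 stood at 24.7 ± 0.643 and 42.8 ± 0.642 CPM (SD, n = 2), a call (adjusted p = 0.0262) lost on leaving out any library of that set (0.0702 to 0.133).

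No class share passed the test between Yap_KO and Yap_WT in the main setting. Goblet-like and Paneth-like shares did not overlap between the groups, and the Paneth-like share passed in some other settings, given below. Enterocyte-like cells made up 25.4 ± 12.7% in Yap_KO and 32.2 ± 9.26% in Yap_WT (SD, n = 2; adjusted p = 0.660 by edgeR), stem and progenitor-like cells 30.0 ± 18.3% and 16.4 ± 2.69% (adjusted p = 0.206), and goblet-like cells 5.46 ± 1.35% and 2.13 ± 0.764% (adjusted p = 0.0888). Paneth-like cells made up 3.26 ± 1.61% and 1.06 ± 0.145% (adjusted p = 0.0841), enteroendocrine-like cells 1.69 ± 1.45% and 0.708 ± 0.0714% (adjusted p = 0.0888), and tuft-like cells 0.585 ± 0.082% and 0.677 ± 0.305% (adjusted p = 0.679). The Yap_KO replicates stood apart, with 43.0% progenitor-like cells in replicate 1 and 17.1% in replicate 2. Without Yap_KO replicate 2, 5 of the 6 classes passed: progenitor-like (log2 ratio 1.39, adjusted p = 0.0140), enterocyte-like (−0.97, 0.0495), goblet-like (1.61, 0.0213), Paneth-like (2.04, 0.00127) and enteroendocrine-like cells (1.93, 0.000545). Unnamed clusters held 42.2% and 51.2% of Yap_WT cells and 25.2% and 40.4% of Yap_KO cells. The largest, cluster 0, had 6 of 12 enterocyte markers raised but low UMIs. It held 721 and 595 Yap_WT cells and 197 and 1125 Yap_KO cells. Unnamed cells counted in the denominator of every share, so enterocyte-like shares leave out such cells.

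In stem and progenitor-like sums, YAP target genes as a list and several repair-associated genes were lower in Yap_KO. Clu (ENSMUSG00000022037, chromosome 14, 65968483 to 65981547) fell 17.3-fold from 3.32 ± 0.794 to 0.181 ± 0.0392 CPM (SD, n = 2; −4.11 ± 0.27 SE, adjusted p = 0.000375). The LIM protein gene Ajuba fell 16-fold, Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) 27.8-fold and the ferlin Myof 11.8-fold. Smaller falls were seen in the scaffold gene Ahnak (6.47-fold), Ccn1 (3.08-fold), Krt7 (2.51-fold), Ly6c1 (2.31-fold), Avpi1 (2.29-fold), the galectin Lgals3 (2.27-fold) and the pyroptosis effector Gsdmd (2.17-fold). Of 16 YAP target genes 6 fell and 1 rose (7 and 2 adjusted over the list alone; median −0.30, camera adjusted p = 0.000226, and 0.580 with an estimated correlation). The repair-associated list did not pass as a whole (7 of 29 lower, 3 higher, 13 and 7 adjusted over the list alone, median −0.13, adjusted p = 0.0800), and its members moved apart. Anxa1 (ENSMUSG00000024659, chromosome 19, 20373428 to 20390944) rose 3.46-fold to 73.8 ± 26.7 CPM (1.79 ± 0.26, adjusted p = 0.0114). Ly6a (2409 ± 550 against 3464 ± 128 CPM, −0.52 ± 0.13, adjusted p = 0.0731), Lgr5 (0.51 ± 0.16, adjusted p = 0.127), Olfm4 (0.76 ± 0.20, adjusted p = 0.0751), Mki67 (0.02 ± 0.09, adjusted p = 0.951), Apoa4 (0.03 ± 0.56, adjusted p = 0.996) and Isg15 (−0.39 ± 0.25, adjusted p = 0.495) did not pass. Lgr5, Olfm4 and Mki67 were among the markers that named the class, which favours similar levels.

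The cells compared lay in different clusters: 1845 of 1959 and 769 of 822 Yap_KO progenitor-like cells were in clusters 6 and 9, against 259 of 648 and 195 of 557 Yap_WT cells. Clusters 1, 4 and 7 held 9 and 15 Yap_KO cells and 357 and 345 Yap_WT cells. Within clusters 6 and 9 alone, Yap1, Ccn2 (−3.25 ± 0.54, adjusted p = 0.0135) and Ajuba (−1.74 ± 0.39, adjusted p = 0.0354) remained lower and Anxa1 higher (3.5 ± 0.33, adjusted p = 0.00175). Clu (−2.49 ± 0.68, adjusted p = 0.0655), Ccn1 (−0.79, 0.310), Myof (−0.56, 0.423), Krt7 (−0.22, 0.243), Ahnak (−0.82, 0.108), Avpi1 (−0.34, 0.320) and Gsdmd (−0.39, 0.278) no longer passed. There Lgals3 stood at 0.49 (0.0742) and Ly6c1 was higher (0.60 ± 0.09, adjusted p = 0.0115). Single libraries also decided calls. Anxa1 stood at 0.0555 and 0.136 without Yap_WT replicates 1 and 2, Ccn1 at 0.0827 without Yap_WT replicate 1, and Gsdmd at 0.103 without Yap_WT replicate 2. Lgals3 stood at 0.186, 0.191 and 0.0864 without Yap_WT replicate 1, Yap_WT replicate 2 and Yap_KO replicate 2. Thinning took all progenitor-like sums to 959702 UMIs, set by a homeostasis library, from between 37404623 and 107279904 UMIs in the Yap libraries. It thus cut depth as well as evening it, and left 8304 genes to test. In total 592 of 13150 genes were called, 285 higher and 307 lower. The count was 136 and 98 without Yap_WT replicates 1 and 2, and 40 after thinning to equal depth.

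**Figure D3:**
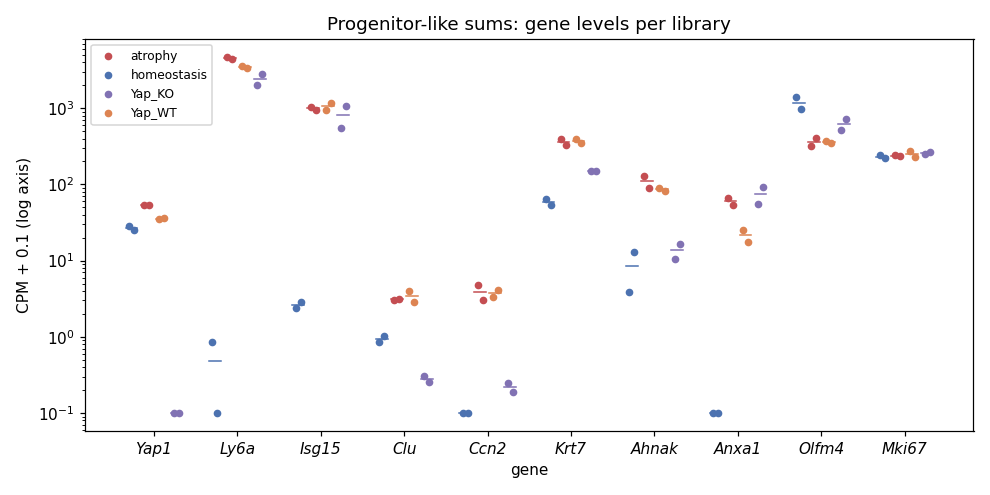
TMM-scaled CPM plus 0.1 (log axis) of 10 genes in stem and progenitor-like sums, 1 point per library and a bar at each group's mean. Yap1, Clu and Ccn2 sit lower in both Yap_KO libraries than in both Yap_WT libraries, Anxa1 sits higher, and Mki67 has means of 232 and 238 CPM in homeostasis and atrophy and of 251 and 255 CPM in Yap_WT and Yap_KO.

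Other gene groups also differed. Antimicrobial genes were higher in Yap_KO progenitors (8 of 20, 10 adjusted over the list alone, median 1.40, adjusted p = 6.04e-05, and 0.580 with an estimated correlation), led by the Paneth cell genes Mptx2 (15.2-fold), Defa21 (8.42-fold), Defa24 (5.58-fold), Defa17 (4.91-fold), Itln1 (4.78-fold) and Lyz1 (4.11-fold). Defa genes are near-identical. The 8 Paneth markers stood at a median of 45.3 and 26.3 CPM in Yap_KO progenitors and 49.3 and 26.1 CPM in Yap_KO enterocytes. These libraries held 4.39% and 2.12% Paneth-like cells against 1.16% and 0.955% in Yap_WT. The calls of Mptx2 (0.0727 and 0.111), Defa17 (0.170 and 0.164), Defa24 (0.213 and 0.270), Itln1 (0.0630 and 0.0683) and Lyz1 (0.225 and 0.230) were lost without Yap_WT replicate 1 or 2, and that of Defa21 without Yap_WT replicate 2 (0.0535). Defa24 and Lyz1 stood at 0.0558 and 0.0512 without Yap_KO replicate 1. Cholesterol synthesis genes were higher in 4 of 20 cases (9 adjusted over the list alone, median 0.27, adjusted p = 5.2e-06, and 0.580 with an estimated correlation), among them Hmgcs1 (1.34-fold) and Msmo1 (1.36-fold). Their adjusted p without Yap_WT replicate 2 were 0.0523 and 0.201, and without Yap_WT replicate 1 or Yap_KO replicate 1 Hmgcs1 stood at 0.174 and 0.0532 and Msmo1 at 0.247 and 0.0985. The cell-cycle regulator gene Rgcc (3.77-fold) and the secretory chaperone Agr2 (3.03-fold) also rose.

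Interferon-stimulated genes (0 of 43 called by edgeR, median −0.35, adjusted p = 6.04e-05) and MHC class I genes (1 of 21 lower, 9 adjusted over the list alone, median −0.37, adjusted p = 4.83e-08) passed as lists toward lower values, each with adjusted p = 0.580 with an estimated correlation. In the same sums edgeR gave 2230 genes of all kinds with an unadjusted p below 0.05 and DESeq2 called 993. The interferon list did not hold its direction: without Yap_KO replicate 1 it lay higher (adjusted p = 0.532, median 0.04). Also passing were digestion genes (1 of 24 lower, Mep1b 2.00-fold, adjusted p = 0.000112, and 0.484 without Yap_KO replicate 1), proliferation genes (1 of 35 lower, Cdc20 1.25-fold, median −0.09, adjusted p = 0.000354) and cell death genes (1 of 23 lower, adjusted p = 0.0108, and 0.532 without Yap_KO replicate 1). Crypt-base genes (0 of 24, 10 higher and 1 lower adjusted over the list alone, median 0.25, adjusted p = 0.00406) and mitochondrially encoded genes (0 of 13, median 0.11, adjusted p = 0.000495) passed toward higher values, as did the unfolded protein response (2 of 18 higher, Herpud1 1.43-fold and Xbp1 1.32-fold, 1 lower, adjusted p = 0.0363, and 0.0727 and 0.493 without Yap_WT replicate 1 and Yap_KO replicate 2). Toward lower values passed lower-villus genes (adjusted p = 0.0402, lost without Yap_WT replicate 1, 0.0628, Yap_WT replicate 2, 0.0540, or Yap_KO replicate 1, 0.138) and MHC class II (adjusted p = 0.0445, and 0.285 and 0.402 without Yap_WT replicate 1 and Yap_KO replicate 1). None of them held with an estimated correlation. Single libraries also decided these gene calls. Cdc20 was lost on leaving out any of the 4 (0.063 to 0.226) and Mep1b without Yap_WT replicate 2 (0.201). Herpud1 was lost without Yap_WT replicates 1 and 2 (0.0885 and 0.163), as was Xbp1 (0.156 and 0.249), which also stood at 0.0657 without Yap_KO replicate 2.

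In enterocyte-like sums 35 of 12521 genes were called, 17 higher and 18 lower. Car2, a cytosolic carbonic anhydrase (ENSMUSG00000027562, chromosome 3, 14886273 to 14900770), fell 3.30-fold from 51.5 ± 7.22 to 15.6 ± 1.09 CPM (SD, n = 2; −1.72 ± 0.14 SE, adjusted p = 0.0122). Wwc1 (Kibra), a Hippo pathway gene, fell 2.07-fold (adjusted p = 0.0307), and the gasdermins Gsdmc4 and Gsdmc2 fell 8.09-fold and 13.2-fold. The Paneth genes Itln1 (4.31-fold) and Mptx2 (13.9-fold) rose, with the level of Paneth markers in progenitors and enterocytes given above. Antimicrobial genes as a list were higher (2 of 19, 11 adjusted over the list alone, median 1.94, adjusted p = 9.05e-12, and 0.0548 with an estimated correlation). Apoa4 (0.15 ± 0.37, adjusted p = 0.918), Alpi (0.02 ± 0.25, adjusted p = 0.995) and Isg15 (0.46 ± 0.55, adjusted p = 0.791) did not differ detectably. Apoa4 and Alpi were among the markers that named the class. Other lists that passed were repair-associated genes (0 of 26, median 0.79, adjusted p = 0.000354, and 0.687 with an estimated correlation), lower-villus genes (2 of 10 lower, 0.000354, and 0.428) and MHC class II genes (0 of 7, 2 lower adjusted over the list alone, median −0.95, 0.000742, and 0.683). A further 5 lists passed with median shifts of 0.46 (proliferation), 0.20 (wound-edge), −0.19 (MHC class I), −0.30 (chemokines and NF-kB genes) and 0.22 (unfolded protein response), with no member called and adjusted p = 0.683 or 0.687 with an estimated correlation. Each lost its call without 1 library: all 5 without Yap_KO replicate 1 (proliferation 0.205, wound-edge 0.15, MHC class I 0.535, unfolded protein response 0.129, and chemokines reversed at 0.275). Wound-edge genes and the unfolded protein response also lost it without Yap_WT replicate 1 (0.115 and 0.202), MHC class I and chemokines without Yap_WT replicate 2 (0.165 and 0.337), and the unfolded protein response without Yap_KO replicate 2 (0.0797). Repair-associated genes stood at 0.0676 without Yap_KO replicate 1. By edgeR 1521 genes had an unadjusted p below 0.05, and DESeq2 called 1062. Thinning took the enterocyte-like sums to 368094 UMIs, set by an atrophy library, from between 31765164 and 68213252 UMIs in the Yap libraries. It left 4864 genes to test. A single gene, Yap1, was called without Yap_WT replicate 1, Yap_WT replicate 2 or Yap_KO replicate 1, and none after thinning to equal depth. Wwc1, Gsdmc4 and Gsdmc2 were also lost without Yap_KO replicate 2 (0.0774, 0.0540 and 0.0571).

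Over the whole epithelium 8 of 15415 genes were called, 1 higher and 7 lower, with 1619 at an unadjusted p below 0.05 and 424 called by DESeq2. Besides Yap1, Ajuba fell (−3.82 ± 0.35 SE, adjusted p = 0.0333), and Ccn2 (−4.52 ± 0.55, adjusted p = 0.0842), Msln (0 and 0 UMIs against 302 and 312, adjusted p = 0.158) and Clu (−1.50 ± 0.98, adjusted p = 0.607) did not pass. The count was 3720 without Yap_KO replicate 2, 11 without Yap_KO replicate 1 and 1 without either Yap_WT replicate, when Ajuba stood at 0.313 and 0.245. Goblet-like sums gave 8 calls among 12067 genes, 5 higher and 3 lower, with 90 and 16 without Yap_KO replicates 2 and 1 and 0 without either Yap_WT replicate.

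Genes that rose in atrophy in the first set were then tested in the second, whose fold changes rest on other libraries. Both contrasts came from a single fit of 8 libraries, so each gene's estimate of the spread was shared between them. Calls in the 2 contrasts were therefore not independent, and the expected counts and Fisher p-values below do not allow for this. Of 1298 genes raised in atrophy progenitors, 103 were lower in Yap_KO progenitors against 30.3 expected from independent calls (odds ratio 4.92, 95% interval 3.81 to 6.32, Fisher's exact test p = 1.12e-30), and 64 were higher against 28.1 expected (odds ratio 2.73, Fisher's exact test p = 2.51e-10). As a list they did not move on balance (median −0.03, camera p = 0.0646, and 0.516 with an estimated correlation), nor did the 1455 genes lowered in atrophy (median −0.04, camera p = 0.209, and 0.567 with an estimated correlation). Across the 13150 genes, which are not independent replicates, the fold changes of the 2 contrasts were unrelated (Spearman's rho −0.00703). Without Yap_KO replicate 2 the raised list passed at the preset correlation (camera p = 0.00152), and without replicate 1 it stood at 0.636. Within clusters 6 and 9 the overlap was the other way, with 13 raised genes among 487 called lower against 48.6 expected (odds ratio 0.24, interval 0.126 to 0.416).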

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

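The comparison on sums thinned to equal depth and the counts of gastric mucous-like and cluster 16 cells were chosen only after the results were seen.

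The atrophy response was tested for a difference between enterocyte-like and progenitor-like sums, and 1723 genes passed by limma at full depth. This number is not read as biology, since the same test called 1293 of 11649 unchanged genes in simulated data; without atrophy replicates 1 and 2 it was 4742 and 5022, and with only the 4 libraries of the set 252. After thinning every sum to 368094 UMIs, 31 of 3999 genes differed, 15 with the higher log2 change in enterocyte-like and 16 in progenitor-like sums, with 621 at an unadjusted p below 0.05. Genes with the more positive change in enterocyte-like sums included Arg2 (a difference of 5.09), Car4 (4.36) and Dmbt1 (2.88), and those with the more positive change in progenitor-like sums included the interferon-stimulated genes Oasl2 (−3.81), Parp12 (−3.29) and Ifi35 (−2.21) and the scaffold gene Ahnak (−3.33), all named after their values were seen. The enterocyte-like sums of atrophy rested on 25 and 24 cells, and 23 of the 25 in replicate 1 lay in homeostasis clusters. Those 23 had a median interferon-stimulated level of 1470 CPM, against 6260 in progenitor-like cells of that library and 11200 in enterocyte-like cells of replicate 2, so the interferon part of this difference is not read as a property of the class.

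Gastric mucous-like cells, led by Tff2, Gkn3 and Ctse and akin to cells of the stomach or of Brunner's glands, numbered 281 in the atrophy libraries (51 and 230, or 1.50% and 4.92%). Homeostasis had 0 of 5414 epithelial cells, which allows a share of up to 0.0554%. Yap_WT held 7 and 3 such cells and Yap_KO 61 and 10. No biological or technical explanation was tested.

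Cluster 16, which had too few class markers to be named and was led by Ly6m, Ly6d, Il33, Ly6g, Clca4a and Lgals3, held 432 cells in the atrophy libraries (258 and 174). Homeostasis had 0 of 5414 cells, with the same upper limits as above, and Yap_WT had 149 and 98 cells against 5 and 1 in Yap_KO. Cluster 19, which shares several leading genes with it, went the other way, with 26 and 14 cells in homeostasis, 2 and 1 in atrophy, 42 and 48 in Yap_WT and 237 and 251 in Yap_KO.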

How the results depend on the processing

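The restriction to named classes or to clusters shared by the 4 libraries, the crossed block, the subtractions of enterocyte RNA, the thinned lists and the thinned response difference were chosen only after the results were seen. Leaving aside the subtractions, which ended the progenitor-like calls of Apoa4 and Apoc3 in atrophy and turned Apoc2 higher at the larger fraction, 83 of 125 calls of a named gene in 1 comparison and class held in every setting, 41 were lost in at least 1 and 2 changed direction (Lgals3 counts under both), and 28 of 56 results of named genes without a call gained one. Over all gene and setting pairs the outcome was the same in 2951, lost in 156, gained in 70, moved in 59 and reversed in 2. For lists the outcome was the same in 517, lost in 173 and reversed in 9. Unless the setting itself removes genes, cells or libraries, the cause of a change was not tested. In simulated data edgeR recovered 7.22% of 2-fold changes in enterocyte-like sums of atrophy, 14.6% in its whole epithelium, which had the most UMIs, and 77% in Yap_KO progenitor-like sums, so depth alone did not set what was seen.

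Shares (log2 ratio) in atrophy changed as follows. With 1000 genes and 10% mitochondrial reads as limits, goblet-like cells reversed (−0.708), Paneth-like fell to 0.598, enteroendocrine-like to −2.43 and tuft to −3.82, while progenitor-like still passed at 3.05. Only 165 and 243 homeostasis barcodes passed these limits. Without a cell filter enteroendocrine-like stood at 2.37 and tuft at 0.191. With each library clustered alone goblet-like stood at 0.965 and enteroendocrine-like at 8.4. At resolution 0.5 enteroendocrine-like (1.05) and tuft (−1.2) passed, and so they did with only the 4 libraries (1.05 and −1.08). In Yap_KO, Paneth-like passed with the strict limits (2.07), without doublet removal (1.74), at resolution 0.5 (1.61) and with cells of at least 5000 UMIs (1.99). Goblet-like stood at −0.7 without a cell filter and tuft at 0.756 with each library alone.

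Thinning took whole-epithelium, enterocyte-like and progenitor-like sums to the smallest sum of the class, which lay in the first set. For Yap_KO it therefore lowered depth as well as evening it. Genes called in whole epithelium of atrophy (11709) numbered 6487 at a mean CPM of at least 10, where fewer genes are tested. In its enterocyte-like sums (2) they were 637 without a count filter, 1 at CPM 10, 940 by DESeq2, 0 with only the 4 libraries, 12 after thinning and 1 at resolution 2, and in progenitor-like sums (5564) 3214 after thinning. In Yap_KO whole epithelium (8) they were 57 without a count filter, 1 at CPM 10, 424 by DESeq2, 0 with only the 4 libraries, 2 after thinning, 3 without a cell filter and 3 with each library alone. In enterocyte-like sums (35) they were 618 without a count filter, 11 at CPM 10, 1062 by DESeq2, 23 with only the 4 libraries, 0 after thinning, 240 with the strict limits, 90 without a cell filter, 118 without doublet removal, 126 with all variable genes and 94 at resolution 0.5. In progenitor-like sums (592) they were 1539, 234 and 993 for the first 3 of these, 40 after thinning and 950 in shared clusters, where Ly6c1 (0.595) and Lgals3 (0.493, adjusted p = 0.0742) reversed. In goblet-like sums (8) they were 439, 1 and 42, then 5 with only the 4 libraries, 16 without a cell filter and 1 with each library alone. Yap1 in whole epithelium of Yap_KO stayed at −10.4 but lost its call with only the 4 libraries (adjusted p = 0.205). The response difference (1723) fell to 252 with only the 4 libraries and to 31 after thinning.

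Lists passing by camera numbered 0 in every class with an estimated correlation. By fry they were 18, 3 and 22 in whole epithelium (11), enterocyte-like (6) and progenitor-like sums (9) of atrophy, and 0, 1, 0 and 0 in whole epithelium (13), enterocyte-like (9), progenitor-like (13) and goblet-like sums (9) of Yap_KO. After thinning 3 passed in Yap_KO enterocyte-like sums. The genes raised and lowered in atrophy passed as sets in Yap_KO progenitor-like sums with a limit of log2 fold change 2 (camera p = 0.0496 and 0.0141 at the preset correlation, against 0.0646 and 0.209). Neither held with an estimated correlation (camera p = 0.515 and 0.395).

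Replicate numbers were used as a block within each set only here, since they are only numbers. The blocked fit called 20 genes in enterocyte-like sums of atrophy, and in Yap_KO 0 in whole epithelium, where Yap1 kept −10.4 (adjusted p = 0.126), 11 in enterocyte-like, 365 in progenitor-like and 14 in goblet-like sums. In clusters 16 and 19 it called 646 genes, 255 higher and 391 lower, against 204. Same-numbered libraries had deviations correlated at 0.05 and −0.27 in whole epithelium of atrophy and Yap_KO, and a block with the numbers crossed called 7 genes in the latter. A call lost under the block is not a smaller effect.

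Leaving out each replicate assumes that the lone library varies like the other groups. In Yap_KO the log2 share ratio ran from −0.607 to 0.343 for tuft, −0.968 to 0.0967 for enterocyte-like, −0.104 to 1.93 for enteroendocrine-like, 0.0583 to 1.39 for progenitor-like, 1.03 to 1.78 for goblet-like and 0.988 to 2.04 for Paneth-like cells. The p of the genes raised in atrophy ran from 0.00152 to 0.636 and the response difference from 1498 to 5022 genes. Calls ran from 0 to 1244 in enterocyte-like sums of atrophy (the highest without atrophy replicate 1), and in Yap_KO from 1 to 3720 in whole epithelium (the highest without Yap_KO replicate 2), 1 to 49 in enterocyte-like, 98 to 762 in progenitor-like and 0 to 90 in goblet-like sums. Yap1 in goblet-like sums ran from −10.6 to −10.1. These are fitted values against a group with no UMI, so only the lower bound given above is read. Lists passing ran from 2 to 9 in enterocyte-like sums of atrophy, and in Yap_KO from 6 to 15 in whole epithelium, 5 to 10 in enterocyte-like and 8 to 18 in goblet-like sums.

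Some lists reversed without Yap_KO replicate 1. Their adjusted p is given with a minus sign where the list was lower, so a range through 0 holds changes in both directions. In whole epithelium it ran from −0.00587 to 5.63e-07 for interferon-stimulated genes, −0.105 to 0.598 for proliferation, −0.0231 to 0.259 for lipid absorption, −0.00466 to 0.908 for cell death and −0.0702 to 0.7 for mitochondrially encoded genes. It ran from −0.337 to 0.275 for chemokines in enterocyte-like sums, −0.00393 to 0.532 for interferon-stimulated genes in progenitor-like sums, and −0.0042 to 0.0459 for interferon-stimulated genes and −0.000743 to 0.963 for MHC class I in goblet-like sums.

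Some settings left too few cells for a test of atrophy: each library clustered alone and the strict limits (enterocyte-like and progenitor-like), no cell filter (enterocyte-like and progenitor-like), and no doublet removal, all variable genes and resolution 0.5 (enterocyte-like).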

Other observations

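The comparison of clusters 16 and 19, the subtraction of enterocyte RNA, the depth test, the interferon test and the enterocyte share test were chosen only after the results were seen, while the test of Paneth RNA was set down before. The criteria of the interferon, share, shared-cluster and digestion and lipid tests were rewritten after their values were seen. The verdicts of the interferon and share tests moved from excluded to open, and those of the shared-cluster and digestion and lipid tests from a fit to open.

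In goblet-like sums of Yap_KO edgeR called 8 genes. Besides Yap1, Wwc2, a Hippo pathway gene related to Kibra (−2.97), and the alarmin Il33 (−2.38) fell, and Reg4 (1.56) and the metallothionein Mt1 (1.50) rose (log2 fold changes, edgeR, n = 2 per group); these genes and the next pair were named after their values were seen. The neutrophil calprotectin genes S100a8 and S100a9 had 720 and 979 UMIs in Yap_KO goblet-like cells, at 35.8 and 26.9 CPM and at 41.7 and 49.1 CPM per library, against 1 and 0 UMIs in Yap_WT. The T and NK cell cluster, which was left out of the epithelium, also had S100a8 and S100a9 among its leading genes, with 14 and 22 cells in Yap_WT and 40 and 25 in Yap_KO. DESeq2 called 42 goblet genes and edgeR gave 857 at an unadjusted p below 0.05, and edgeR called 0 without either Yap_WT replicate and 90 without Yap_KO replicate 2. YAP target genes (5 of 14 lower adjusted over the list alone, median −0.71, camera adjusted p = 3.07e-05), digestion genes (median −1.06, 3.68e-10), lipid absorption genes (−0.51, 0.000543), lower-villus genes (−0.64, 0.000629), MHC class I (−0.24, 9.53e-06) and interferon-stimulated genes (−0.36, 3.14e-07) were lower as lists, and cholesterol synthesis (0.16, 0.0299), the unfolded protein response (0.26, 0.00182) and glycolysis (0.24, 3.07e-05) higher. The adjusted p was 0.423 for glycolysis and 0.784 for each of the others with an estimated correlation, and without Yap_KO replicate 1 the interferon list was higher (0.0459) and MHC class I stood at 0.963. Lipid absorption was lost without Yap_WT replicate 1 (0.5) or Yap_KO replicate 1 (0.674), lower-villus genes without Yap_KO replicate 1 (0.0582), and the unfolded protein response without Yap_WT replicate 2 (0.126). Cholesterol synthesis was lost without Yap_WT replicate 1 (0.0527), Yap_WT replicate 2 (0.143) or Yap_KO replicate 2 (0.345). In Paneth-like sums only Yap1 was called (727 at an unadjusted p below 0.05, 26 by DESeq2), with 40 and 11 calls without Yap_KO replicates 1 and 2, and in enteroendocrine-like sums edgeR called 0 genes (524 at an unadjusted p below 0.05, 2 by DESeq2), with 11 without Yap_WT replicate 1.

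The unnamed clusters 16 and 19 shared Ly6d, Ly6m, Clca4a, Pmp22 and Gprc5a among their leading genes, and Yap_KO cells lay mostly in cluster 19 (237 and 251 cells, against 5 and 1 in cluster 16) where Yap_WT cells lay mostly in cluster 16 (149 and 98, against 42 and 48). Summed over both, 204 genes were called in Yap_KO against Yap_WT, 71 higher and 133 lower. Lower genes included Krt7 (−2.45 ± 0.219 SE, adjusted p = 0.00385), Wwc1 (−2.75 ± 0.184, 0.00139), Ptpn21 (−3.48 ± 0.234, 0.00139), Ajuba (−7.79 ± 0.539, 0.00139), Clu (−5.59 ± 0.631, 0.0101), Myof (−3.37 ± 0.326, 0.0065) and Msln (39.1 and 33.4 CPM in Yap_WT, 0 and 0 in Yap_KO), and Mt1 was higher (3.37 ± 0.23, 0.00139). YAP target genes were lower in 7 of 15 cases (camera adjusted p = 9.58e-08, and 0.648 with an estimated correlation), repair-associated genes in 6 of 31 (4.81e-06, and 0.897) and proliferation genes in 3 of 35 (4.22e-14, and 0.897). Antimicrobial genes, which include Paneth cell genes, were higher in 8 of 19 (median 1.9, 3.14e-11, and 0.648) and cholesterol synthesis genes in 1 of 20 (median 0.29, 0.0103, and 0.897). The count was 13 without Yap_WT replicate 1, 11 without Yap_WT replicate 2 and 128 without Yap_KO replicate 1.

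Genes lower in atrophy progenitors could reflect enterocyte RNA in the few homeostasis progenitors. One source would add the same fraction of the enterocyte level to every gene. It was taken as 3.86%, the 10th percentile over 244 abundant enterocyte genes, and a smaller fraction would leave at least as many genes above it. Of the 1455 genes lower by over 1 log2 unit, 1447 had UMIs in homeostasis enterocytes, and of these 91.7% lay above 3 times that fraction of their enterocyte level, which argues against this source for the whole set, and 1402 of the 1698 lower genes still tested stayed lower after thinning to 959702 UMIs, which argues against depth. For digestion and lipid absorption genes alone, the size of the fraction decides. A source with the mean enterocyte profile should add no more than the lowest ratio among abundant genes, measured as 0.753%. That ratio is the lowest of 244 from homeostasis sums of 27 and 23 cells, so sampling may have made it too low. After its subtraction 29 of 31 members stayed lower. At 3.86%, which needs a source with another profile unless the lowest ratio is too low, 14 did. Such a source cannot be told apart for those falls, and the second fraction and the split of the pattern were set after the first result was seen.

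The overlap of genes raised in atrophy and lower in Yap_KO progenitors may come from where the cells lie. Within the clusters that hold at least 20 cells of each library the odds ratio was 0.24 (0.126 to 0.416), against 4.92 over all clusters. The clusters were made from expression, with 35 of the 103 overlap genes among the genes used, so the restriction could lower the overlap by itself and this source cannot be told apart. A larger part of uninjured gut in Yap_KO cannot be told apart, since the enterocyte-like shares of 34.4% and 16.5% there overlap those of Yap_WT (25.6% and 38.7%) and Yap_KO progenitors lie in the clusters of homeostasis progenitors. A weaker interferon response cannot be told apart either: in replicate 1 interferon-stimulated genes (−0.89) fell like the pattern (−0.95), while in replicate 2 they did not fall (0.06 against −0.92; median over both −0.31, SD 0.18, against −0.96). The overlap stayed without replicate 1 (odds ratio 5.49 over genes tested in both sets) and without the interferon and MHC lists (102 genes, odds ratio 5.07), so the pattern was also present where those genes did not fall, in 1 library.

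Higher Paneth cell genes in Yap_KO progenitors and enterocytes may come from free RNA of Paneth-like cells. Free RNA would set a shared floor in these 2 classes, and the median level of 8 Paneth markers in progenitors over that in enterocytes was 0.919 in Yap_KO replicate 1 and 1.01 in replicate 2, close to 1 as this source predicts. In Yap_KO, goblet-like (434 and 518 CPM), tuft-like (198 and 38 CPM) and enteroendocrine-like cells (116 and 53.2 CPM) stood above the 45.3 and 26.3 CPM of progenitors. A shared floor does not account for these higher levels. In Yap_WT these classes stood at 443 and 944, 140 and 10.6, and 15 and 11.1 CPM. Goblet-like cells thus showed no rise in Yap_KO, and their level does not bear on the source of the rises in progenitors and enterocytes. No biological explanation of these rises was tested.

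In atrophy replicate 1, 23 of 25 enterocyte-like cells lay in homeostasis clusters. Their median level of interferon-stimulated genes was 1470 CPM, against 1730 and 1580 in homeostasis enterocyte-like cells, 6260 in progenitor-like cells of the same library and 11200 in enterocyte-like cells of atrophy replicate 2. None of their barcodes occurred in homeostasis libraries.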
